A study of Homo sapiens with 17 samples.

How the data were processed

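RNA was measured in IMR32, a human neuroblastoma cell line with amplified MYCN, carrying a doxycycline-inducible construct for the intracellular domain of the receptor NOTCH3 (NOTCH3IC), the active form of the receptor. Per the labels, doxycycline was added to the medium of 2 independent clones, c6 and c8, and 1 array was hybridised per clone and time point. Clone c6 was sampled at times 0, 4, 8, 12, 24, 48, 72, 96 and 120 (9 arrays) and clone c8 at times 0 to 96 (8 arrays). The labels give the times without a unit, so they are printed as labelled. The 17 arrays include no culture kept without doxycycline after time 0, so time in culture and doxycycline run together with NOTCH3IC in every comparison.

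The deposited values are probe set intensities on a linear scale, and the submitters' processing notes name MAS5 and GCOS, without versions. From the values, each array had been scaled to the same 2% trimmed mean of 100.01. The array medians were 14.6, 17.8, 15.5, 19.3, 17.9, 15.5, 17.5, 18.7 and 16.8 in clone c6 and 16.7, 15.4, 16.1, 17.8, 16.3, 17.9, 15.7 and 18.3 in clone c8, in order of time. The scanner files and detection calls were not used here. The number of arrays, not a counting depth, limits the precision.

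Of 54675 probe sets, 41097 had 1 gene symbol in the platform annotation, 1801 had several and 11777 had none listed. Symbols were looked up by gene identifier in a RefSeq gene table of assembly GRCh38.p14, which held 41043 of the 41097 and changed none, so symbols are as annotated. The genome build behind the probe annotation is not given in the sources used here, so no coordinates are printed. Intensities were transformed as log2(value + 16), and fold changes are on that scale, which understates changes of dim genes. Each gene was represented by its probe set of highest mean log2 value, and genes were kept when that mean reached the 40th percentile of all probe sets (4.68). This left 13675 of 19775 genes. No between-array normalization was added to the deposited scaling.

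Tests were made with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Change over time, late against start and early against start came from 1 fit over all 17 arrays with a term for each time point and a term for the clone, which had 7 residual degrees of freedom. Early stands for times 4, 8 and 12, late for times 48, 72 and 96, and start for time 0. Late against early used those 12 arrays with the clone as a term (9 degrees of freedom). The clone difference in response was the interaction of clone and phase on the same arrays (8 degrees of freedom). The clone difference in level used the 16 arrays of shared times with time as a term (7 degrees of freedom). Where phases are compared, arrays of neighbouring times stand in as replicates. The labels do not say whether each time point was a separate culture, so p-values measure the spread between these arrays. Pairing by clone comes from the labels; the clone differences at the shared times correlated with each other between 0.13 and 0.49 across genes, and the clone stayed in the model. No pair of arrays had more than 1.42% of values equal, so all arrays were kept as separate samples.

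A set of 36 gene lists, fixed before the data were examined, was tested with camera at a preset inter-gene correlation of 0.01. The lists were also tested with the correlation estimated per list and with fry. The designs, the lists and the other settings were fixed before the data were examined, and the few settings added afterwards are named as such. Camera compares a list with all other genes, whereas fry asks whether the genes of a list move, on balance, one way and compares them with no other genes; its mixed form asks whether they change in either direction. Named genes followed a fixed rule. For late against start these were the 10 largest rises and 10 largest falls past the threshold with all 6 late arrays on the same side of their own time 0. For early against start they were the 5 largest each way by the same rule. For late against early they were the 5 largest each way whose late and early arrays did not overlap in either clone, and for the clone comparisons the 5 largest each way. Up to 4 members of smallest p in late against start were named per list, besides genes fixed by name (NOTCH3, HES1, HES4, HES5, HEY1, HEY2, HEYL, NRARP, PHOX2A, HAND2, GATA3, DBH, TH, MYCN, PRRX1, SNAI2, VIM, FN1, CD44, MKI67 and CCND1). Of these, TH and CD44 were below the intensity filter. A further gene fixed by name is not reported here.

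The alternatives were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets, eBayes without a trend, no clone term, phase means, each clone alone, and each array left out in turn. On simulated arrays with the real means and residual spread, 100 of 13675 genes changed 2-fold and 100 changed 4-fold. Late against start recovered 83.0% of 2-fold and 98.0% of 4-fold changes, and 16 unchanged genes were also called. Recovery of 2-fold changes was 86.0% for early against start, 97.0% for late against early, 80.0% for any change over time, 99.0% for the clone level and 56.0% for the clone difference in response. Unchanged genes called numbered 9 for early against start, 9 for late against early, 7 for any change over time and 5 for the clone response. The simulated arrays held no change between the times of a phase. Late against early and the clone difference in response pool those times, so their recovery is overstated for genes that moved within a phase. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.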

Results

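Gene expression was followed in IMR32 neuroblastoma cells after doxycycline induction of NOTCH3IC, the intracellular domain of NOTCH3 that enters the nucleus and activates transcription. The series sets a time course of 9 points in clone c6 beside 1 of 8 points in clone c8, with a single array at each point. The title of the series places NOTCH3 in the control of motility in neuroblastoma, and the comparisons below ask which genes changed after induction, when, and whether the clones responded alike. Values are scaled array intensities (signals), and log2 changes are given ± the standard error of the limma fit over the arrays named.

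NOTCH3 itself rose after induction in both clones. The signal of its brighter probe set went from 94.6 at time 0 to 428 ± 37.1 (SD, n = 3 late arrays) in clone c6 and from 218 to 778 ± 67.6 (SD, n = 3 late arrays) in clone c8, a log2 change of 1.88 ± 0.19 late against start (limma adjusted p = 1.03e-05, all 6 late arrays higher). In the early phase the change was 0.74 ± 0.19 (adjusted p = 0.0556). The signal of clone c6 was 75.2 at time 4, below its time 0, and 161 at time 8, while that of clone c8 was 275 and 440. The NOTCH3 signal of clone c8 was the higher at each of the 8 shared times. The other NOTCH3 probe set stayed dim, with a log2 change of 0.00 ± 0.18. Which part of the transcript either probe set reads, and whether it detects the induced construct, is not given in the sources used here.

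The early phase was led by canonical Notch targets. HEY1, a transcriptional repressor directly activated by Notch, rose 37.0-fold early against start (log2 5.21 ± 0.27, adjusted p = 5.23e-08), and HES1, its best-known relative, rose 16.5-fold (log2 4.04 ± 0.33, adjusted p = 8.29e-06) from a start below a signal of 16 in both clones. The other large rises were CXCR4, the chemokine receptor that guides cell migration (13.2-fold), the Notch ligand JAG1 (12.2-fold) and the cell cycle inhibitor CDKN1C (7.22-fold). The largest falls were those of ZNF367 (log2 -1.46 ± 0.27), NANOS1 (-1.32 ± 0.19), CT75 (-1.18 ± 0.22), CCNE2, which encodes cyclin E2 (-1.15 ± 0.17), and PLPPR4 (-1.02 ± 0.14). All 6 early arrays lay on the same side of their own time 0 for each of these genes.

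Of the 16 measured Notch target genes, 7 rose, 1 fell and 8 did not pass early against start, and 8 rose and 1 fell when adjusted over the list alone. HES4 (log2 1.60 ± 0.17) and HEY2 (1.60 ± 0.30) were among the risen and CCND1, encoding cyclin D1, fell by 0.61 ± 0.12. HEYL, at 0.58 ± 0.29, did not pass early (adjusted p = 0.396). The list stood above other genes by camera (adjusted p = 3.01e-08; adjusted p = 0.0999 with an estimated correlation). Genes of DNA replication and S phase went the other way: 6 of 33 fell, 22 when adjusted over the list alone, among them E2F1 (-0.71 ± 0.14) and CDC6 (-0.75 ± 0.16), with a camera adjusted p of 3.63e-20 and an adjusted p of 0.375 with an estimated correlation. Adrenergic transcription factors, which set sympathetic neuroblast identity, were also called lower (3 of 18 fell, 1 rose; camera adjusted p = 0.00237, and adjusted p = 0.0999 with an estimated correlation). SATB1 (-0.70 ± 0.08 late, -0.58 early) and DACH1 (-1.09 ± 0.15 late, -0.92 early) fell in both phases.

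Over all genes, 275 of 13675 changed early against start, 176 higher and 99 lower, and 69 of the risen and 5 of the fallen changed 2-fold or more. Camera called 12 of the 36 lists, and with an estimated correlation 0. The gene count rested on the 2 time-0 arrays: it was 24 without that of clone c6, 47 without that of clone c8 and 63 with the clone left out of the model. It was 178 or 152 without time 4 or time 8 of clone c8, 425 without time 12 of clone c6, and 91 with phase means. That fit has a term for each phase in place of each time point, so the single arrays of a phase serve as its replicates. With phase means in a single clone, which leaves 1 time-0 array as the start, it was 4 in clone c6 (HEY1, HES1, CXCR4 and, outside the naming rule, RGS4) and 15 in clone c8.

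By the late phase, genes of smooth muscle, pericytes and the extracellular matrix were among the largest rises, beside JAG1 and HEY1. The fibrillar collagen COL3A1 rose 188-fold (log2 7.56 ± 0.44, adjusted p = 1.25e-07), from a signal of 8.40 to 5075 ± 1622 (SD, n = 3 late arrays) in clone c6 and from 10.2 to 4617 ± 320 (SD, n = 3 late arrays) in clone c8. ACTA2, the actin of smooth muscle, rose 59.0-fold, TAGLN, an actin-binding protein of smooth muscle, 28.5-fold, and RGS5, a pericyte marker, 27.5-fold. JAG1 (90.7-fold) and HEY1 (46.3-fold) stayed high. TMEM100 (16.3-fold), TNMD, which encodes tenomodulin (15.6-fold), MYC (14.8-fold) and the small leucine-rich proteoglycan LUM (14.4-fold) completed the 10 largest rises, and each was higher on 6 of 6 late arrays. COL3A1, TAGLN, TNMD, MYC and LUM started below a signal of 16 in both clones, so the pseudocount sets much of their fold. With pseudocounts of 1 and 64 on the same probe sets, settings added after seeing the data, the log2 change of COL3A1 was 8.85 and 6.04. Detection calls were not used here.

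**Figure D1:**
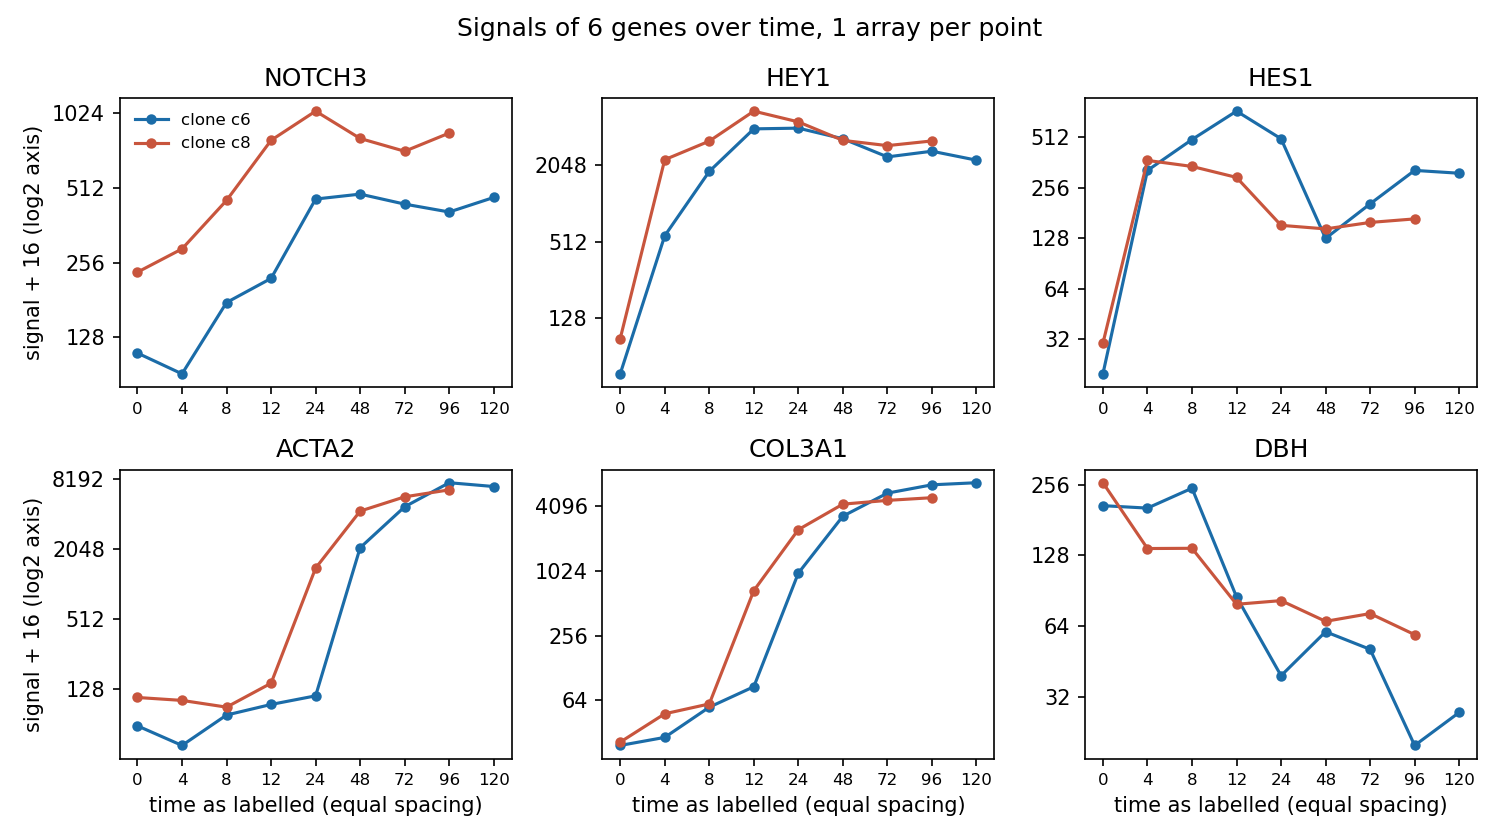
Signals of 6 genes (signal + 16, log2 axis; the axis range differs between panels) against time as labelled, with time points equally spaced; each point is 1 array, blue for clone c6 and red for clone c8. HES1 was highest at time 12 in clone c6 and time 4 in clone c8, whereas the ACTA2 signal was 96.2 at time 24 and 2094 at time 48 in clone c6, and 128 at time 12 and 1393 at time 24 in clone c8.

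The largest late falls were smaller. DBH, the enzyme that makes noradrenaline, fell 4.57-fold (log2 -2.19 ± 0.34, adjusted p = 0.000546). NANOS1 fell 3.22-fold, the immediate early gene EGR1 2.94-fold, the calcium-binding protein gene CALB1 2.89-fold, HSPA12A 2.72-fold, CYYR1 2.56-fold, STC1 2.50-fold, tissue factor F3 2.49-fold, CKM 2.38-fold and ZNRF3, a negative regulator of WNT receptors, 2.33-fold. The log2 standard errors of these falls lay between 0.13 for CYYR1 and 0.34 for DBH. MYCN, the oncogene amplified in this line, changed by -0.13 ± 0.08 (adjusted p = 0.475) and GATA3 by -0.22 ± 0.10 (adjusted p = 0.278).

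Of 12 measured smooth muscle and pericyte markers, 8 rose late against start and none fell, also when adjusted over the list alone; MYH11, smooth muscle myosin, rose by 2.58 ± 0.25 (camera adjusted p = 5.28e-13; adjusted p = 0.0278 with an estimated correlation). Of 34 extracellular matrix genes, 20 rose and 0 fell (23 and 1 adjusted over the list alone), including FN1, fibronectin (2.98 ± 0.29), and the basement membrane collagen COL4A1 (2.06 ± 0.20); camera gave an adjusted p of 2.61e-17, and the adjusted p was 0.0331 with an estimated correlation. Beside these, 5 of 9 measured fibroblast markers rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 3.55e-07, adjusted p = 0.0783 with an estimated correlation). The risen ones include COL3A1 and LUM, which the matrix list also holds, S100A4 (2.61 ± 0.22) and THY1 (1.27 ± 0.14), while COL1A1 (0.49 ± 0.29) and COL1A2 (0.57 ± 0.22) did not pass.

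Genes of cell adhesion rose as well. Of 28 focal adhesion and integrin genes 12 rose and 0 fell (12 and 2 adjusted over the list alone), with vinculin VCL at 1.43 ± 0.11, the integrin ITGA9 at 2.09 ± 0.20, TGFB1I1 at 1.28 ± 0.15 and FERMT2 at 1.15 ± 0.13 (camera adjusted p = 1.56e-05; adjusted p = 0.0413 with an estimated correlation). Of 39 actin cytoskeleton genes 13 rose and 0 fell (15 and 0 adjusted over the list alone), led by tropomyosin TPM1 (2.75 ± 0.20) and the actinin ACTN1 (1.60 ± 0.14; camera adjusted p = 1.97e-07, adjusted p = 0.0750 with an estimated correlation). Of 33 axon guidance genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them the chemokine CXCL12 (2.48 ± 0.17), its receptor CXCR4 (3.11 ± 0.26), the ephrin EFNB2 (2.20 ± 0.16) and SEMA6D (1.42 ± 0.19; camera adjusted p = 5.35e-08, adjusted p = 0.0506 with an estimated correlation).

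Notch targets were still high late: 9 of 16 rose and 1 fell (10 and 2 adjusted over the list alone), HEY2 reaching 3.13 ± 0.30, HEYL 2.46 ± 0.29, HES4 2.39 ± 0.17 and NRARP 1.13 ± 0.16, while HES5 (0.54 ± 0.27) did not pass (camera adjusted p = 7.10e-09; adjusted p = 0.0331 with an estimated correlation). Camera did not call the Notch receptors, ligands and machinery as a list (3 rose and 3 fell of 24, adjusted p = 0.822), whereas fry did (adjusted p = 0.00863). JAG1 and the coactivator MAML2 (1.81 ± 0.18) rose, and the glycosyltransferase MFNG (-1.22 ± 0.20) and the ligand DLL3 (-0.94 ± 0.18) fell. Of 21 genes of the TGF-beta and BMP response 8 rose and 0 fell (8 and 1 adjusted over the list alone), with the receptor TGFBR2 at 2.40 ± 0.23 and the inhibitors of differentiation ID4 at 2.40 ± 0.24, ID3 at 2.29 ± 0.15 and ID1 at 1.06 ± 0.10 (camera adjusted p = 6.82e-06; adjusted p = 0.0439 with an estimated correlation).

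Adrenergic transcription factors fell on balance (7 of 18 fell, 2 rose; 8 and 2 adjusted over the list alone; camera adjusted p = 1.31e-05, adjusted p = 0.0278 with an estimated correlation). PHOX2A fell by 0.77 ± 0.13, HAND1 by 1.09 ± 0.15 and DACH1 by 1.09 ± 0.15, and HAND2 was at -0.03 ± 0.19. GATA2, a factor of the same lineage, instead rose by 1.44 ± 0.18 on its brightest probe set. Its dimmer probe sets disagreed, at 0.79 ± 0.22 and -0.13 ± 0.19. The catecholamine and secretory granule list split, with 3 of 15 members higher and 3 lower (3 and 4 adjusted over the list alone) and no call (camera adjusted p = 0.802): DBH and the noradrenaline transporter SLC6A2 (-0.78 ± 0.17) fell, and CADPS (2.04 ± 0.18) and SCG2 (2.05 ± 0.27) rose. Neuronal cytoskeleton and synapse genes were not called (4 of 26 rose, 2 fell; camera adjusted p = 0.786), although GAP43 rose by 1.53 ± 0.17, DCX by 1.49 ± 0.24 and STMN2 by 1.23 ± 0.21.

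Camera did not call the mesenchymal transcription factors as a list (3 of 16 rose and 1 fell, adjusted p = 0.505), whereas fry did (adjusted p = 0.0263). SNAI2 rose by 0.99 ± 0.13, TWIST1 fell by 0.52 ± 0.11 and PRRX1 was at 0.09 ± 0.24. Mesenchymal surface and cytoplasmic markers were called (5 of 15 rose, 1 fell; 7 and 2 adjusted over the list alone; camera adjusted p = 0.00576), a call lost with an adjusted p = 0.177 with an estimated correlation; LGALS1, galectin-1 (2.67 ± 0.28), and the cadherin CDH11 (2.40 ± 0.23) led it, and VIM rose by 0.39 ± 0.10. CD44, a mesenchymal marker, stayed too dim to be tested.

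**Figure D2:**
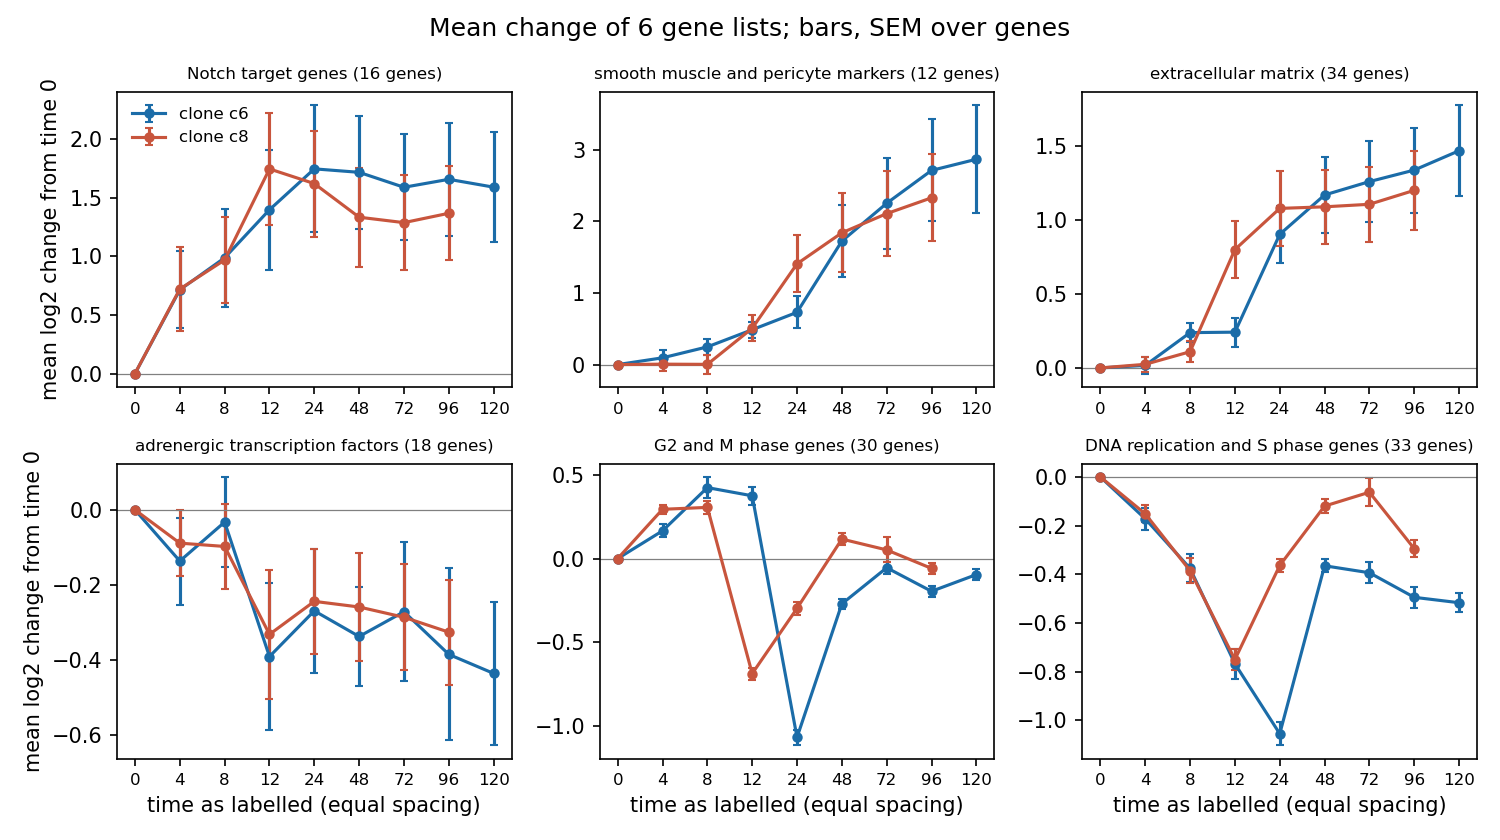
Mean log2 change from the clone's own time 0 of 6 gene lists against time as labelled, with time points equally spaced; each point is 1 array, bars are the SEM over the genes of the list, blue is clone c6 and red clone c8, and the axis range differs between panels. The G2 and M phase list was lowest at time 24 in clone c6 (-1.07) and time 12 in clone c8 (-0.69).

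In all, 949 genes changed late against start, 712 higher and 237 lower, and 355 of the risen and 35 of the fallen changed 2-fold or more; median centring of the arrays gave 592 higher and 462 lower. Camera called 17 of the 36 lists, 13 higher and 4 lower. With an estimated correlation 6 held: Notch targets, extracellular matrix, focal adhesion, smooth muscle and pericyte markers, the TGF-beta and BMP response and adrenergic transcription factors. Fry called 16 lists, 15 higher and 1 lower. These include the Notch receptors, ligands and machinery, the WNT response and mesenchymal transcription factors, which camera did not call. Called by camera but not by fry were S phase genes (fry adjusted p = 0.121), MYC and MYCN targets (0.190), p53 targets (0.0885) and histone genes (0.0588). The gene count was 393 without the time-0 array of clone c6, 373 without that of clone c8 and 506 with the clone left out of the model. With phase means 743 genes passed over both clones, 303 in clone c6 alone and 93 in clone c8 alone, each single clone with 1 time-0 array as the start.

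Late against early, a comparison that does not use time 0, set apart the genes that moved after the early phase. COL3A1 was 59.4-fold and ACTA2 56.3-fold higher late than early, TAGLN 26.1-fold and RGS5 15.6-fold, and TNMD was higher by 4.00 on the log2 scale, with log2 standard errors of 0.26 to 0.51. As COL3A1, TAGLN and TNMD started below a signal of 16 in both clones, the pseudocount may set part of their change here too. DBH was 2.67-fold lower, CKM 2.30-fold, the interferon-induced gene IFI44 2.05-fold, SLC6A2 1.99-fold, and the imprinted gene DLK1 was also lower (adjusted p = 0.000274). In each clone every late array of these genes lay beyond every early array. HES1 was lower late than early (log2 -1.18, adjusted p = 0.00170) while still 7.28-fold above time 0, and HEYL was higher (1.88, adjusted p = 0.000471). HEY1 did not differ between the phases by more than the spread (0.32, adjusted p = 0.733).

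Here 8 of 12 smooth muscle and pericyte markers rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 5.69e-14, adjusted p = 0.0470 with an estimated correlation). Of 34 matrix genes 17 rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 2.00e-19, adjusted p = 0.0470 with an estimated correlation). Of 9 fibroblast markers 4 rose (5 adjusted over the list alone; camera adjusted p = 4.79e-06, adjusted p = 0.117 with an estimated correlation). Notch targets were not called as a list by camera (3 of 16 rose and 2 fell, camera adjusted p = 0.0756). Of all genes, 708 passed, 515 higher and 193 lower late than early, and median centring gave 447 and 319. Camera called 16 lists, 2 of them with an estimated correlation. The gene count was 1244 without time 12 of clone c8 and 179 in clone c8 alone.

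Across all time points, 904 of 13675 genes varied. Of the 355 genes that rose 2-fold or more late against start, 15 had passed 2-fold by time 4 in clone c6 and 33 in clone c8, 116 and 242 by time 12, and 242 and 310 by time 24. As a percent of each clone's own late change, the mean change of these genes was 21.7% in clone c6 and 30.8% in clone c8 at time 8, 44.6% and 85.4% at time 12, and 79.1% and 103% at time 24. At time 4 it was 9.91% and 19.8%. The genes were chosen for their change from time 0, and a chance low value on a time-0 array would move every percent of that clone toward 100%. The difference between the clones was not tested for single genes. The count of varying genes was 556 or 573 without the time-0 array of clone c6 or c8, and 369 with the clone left out of the model.

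The late change from the clone's own time 0 correlated between clones with r = 0.71 (Spearman's rho = 0.44) across 13675 genes, which are not independent replicates. Of 470 genes that changed 2-fold or more in clone c6, 464 (98.7%) changed in the same direction in clone c8; 293 of 417 risen genes also rose 2-fold in clone c8 and 15 of 53 fallen genes also fell 2-fold. In limma, no gene passed for a difference in late minus early change (0 of 13675), with 1193 genes at an unadjusted p under 0.05 where 684 were expected by chance and a smallest adjusted p of 0.216. Simulated differences were recovered in 56.0% of cases at 2-fold and 88.0% at 4-fold in this comparison. The simulation held no change between the times of a phase. These shares therefore overstate what could be found for genes that moved within a phase. Without time 12 of both clones, a setting added after seeing the data, 1 gene passed, SYNPO2 (log2 difference of clone c8 from clone c6 -1.75, adjusted p = 0.0155), named only after its value was seen.

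Apart from the response, the clones differed in level. Clone c8 had higher signals of PAGE1, a cancer-testis antigen gene (7.77-fold), RAC3 (5.35-fold), the splicing factor PHF5A (3.30-fold), TAF15 (3.09-fold) and LINGO1 (2.58-fold). It had lower signals of the GTPase RAB31 (5.11-fold), LRRN3 (4.12-fold), the imprinted gene MEST (3.03-fold), the protease ADAMTS5 (2.82-fold) and NPTX1, neuronal pentraxin (2.79-fold). In total 2963 genes differed, 1562 higher and 1401 lower in clone c8, and 37 and 26 of these by 2-fold or more. The TAF15 difference rests on 1 of its 4 probe sets: the other 3 lay between -0.05 and -0.01 on the log2 scale. With a pseudocount of 1 another had the highest mean and stood for the gene (log2 -0.06, adjusted p = 0.834), whereas the first probe set kept its difference (1.95). A measure of RNA and labelling and a hybridisation control both moved with the clone. The ratio of the 3' to the 5' ACTB control probe set was 1.22 to 1.49 in clone c6 and 1.56 to 1.70 in clone c8. The BioB hybridisation spike read 125 to 201 in clone c6 and 212 to 264 in clone c8. The labels give no hybridisation batch, and a batch that followed the clone could not be told apart from it.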

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

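The gene list tests of the clone difference were fixed beforehand; the tests of arrays exchanged or misplaced, of the NOTCH3 rise, of scaling and of random lists were chosen after the results were seen. Each time point held at most 2 arrays, too few to test a single array against the others of its time.

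For 6 gene lists the late minus early change differed between the clones by camera: G2 and M phase (adjusted p = 4.86e-10), cholesterol biosynthesis (1.85e-07), MYC and MYCN targets (0.000647), DNA replication and S phase (0.00106), the integrated stress response (0.00224) and axon guidance (0.0278). None of the 6 held with an estimated correlation, where the adjusted p was 0.309 for the cholesterol list and 0.803 for the other 5. The early phase of clone c8 includes its time 12 array, where the G2 and M phase list was low (-0.69), as described below. The mean late minus early change of the cholesterol list was higher by 0.37 in clone c8 than in clone c6 on the log2 scale. For this difference 8 of its 19 genes passed when adjusted over the list alone, but none over all genes. Opposite movements against time 0 were seen for 3 named genes, and these differences were not tested. On all 3 late arrays LRRN3 lay below time 0 in clone c6 (-0.19 ± 0.06, SD) and above it in clone c8 (0.71 ± 0.02), a difference of 0.90, while PRRX1 (difference of clone c8 from c6 -1.19) and the haematopoietic marker ITGAM (-0.89) went the other way, both at signals near the intensity filter. Each rests on the time-0 array of its clone.

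Probe sets outside the gene-level results also carried signal: of 6199 probe sets with no gene symbol or several, 166 changed late against start, 130 higher and 36 lower (2.68%, against 5.22% of the 26606 probe sets with 1 symbol).

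The risen genes ran ahead in clone c8 at times 12 and 24, while its leads of 9.87 and 9.11 points at times 4 and 8 lay within 2 spreads (8.32 each) between late arrays. That spread holds neither the error of the time-0 arrays nor that of the early arrays, so it is only a rough yardstick for these leads. At time 12 clone c8 led by 40.8 percentage points of its own late change, with 304 of 355 genes further along than in clone c6. An exchange of the time 12 and 24 arrays of clone c8 does not account for that lead, which undoing it would raise to 58.9 points. For the lead at time 24, which it would lower from 24.3 to 6.25 points, it stays open: over the other genes 1 of 2 distances was shorter in the labelled order, although over all genes the arrays matched times 24 and 48 of clone c6 best, in that order. An array of clone c6 standing in for clone c8 is argued against by the clone differences, whose slope on those at other times was at least 0.70 at both times (0 would mark a c6 array). An earlier rise of NOTCH3 stays open, since NOTCH3 was further along in clone c8 at 4 of the 4 times but is itself a risen gene, and 120 of the 355 were further along at all of them; other clonal differences stay open too.

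Cell division genes were low at time 24 of clone c6 and time 12 of clone c8: all 30 measured G2 and M phase genes lay below time 0 (mean log2 change -1.07 and -0.69), as did 33 and 32 of 33 S phase genes (-1.06 and -0.75), against 1 of 8 histone genes on each array (1.27 and 1.31, no gene tested singly). The G2 and M phase list had been above time 0 before, at 0.17, 0.42 and 0.37 at times 4, 8 and 12 of clone c6 and 0.29 and 0.30 at times 4 and 8 of clone c8. S phase genes had fallen step by step from time 4 (-0.17 in clone c6, -0.15 in clone c8) and stood at -0.37, -0.39 and -0.49 at times 48, 72 and 96 in clone c6 but at -0.12, -0.06 and -0.29 in clone c8. Scaling between arrays does not account for it, the G2 and M phase list staying at -0.67 or lower under quantile normalization. Of 10000 random lists matched on mean expression, 0 lay as low on either array. These arrays were picked because the list was lowest there, so that count adds little. Random lists lack the shared movement of cell cycle genes, so for the G2 and M phase list a difference in culture state at a single harvest stays open, and an exchange of the clone c8 arrays would place its low point at time 24 as in clone c6; no biological explanation was tested.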

How the results depend on the processing

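The settings without time 12 of both clones, pseudocounts of 1 and 64 on the same probe sets and the omission of single late arrays from the clone agreement were added after seeing the data. Pseudocounts of 1 and 64, quantile normalization, median centring and the stricter filter left the total counts of genes and lists within 1.5 times, as did time 120 counted as late, run only for late against start (1050) and late against early (932). Median centring raised the lower genes from 237 to 462 late against start and from 193 to 319 late against early. Testing all probe sets, which are more numerous than genes, gave 1478 that varied with time, 1556 for late against start, 436 for early against start, 1100 for late against early and 6252 for the clone level. The count of genes varying with time was 599 with the mean of a gene's probe sets and 591 without an intensity trend. Early against start was the least stable count, with 140 genes without a filter, 146 without a trend, 91 with phase means and 85 without time 12 of both clones. Without those 2 arrays late against early gave 1213 genes and the clone difference in response 1. With phase means late against start gave 743 genes. Phase means in clone c6 alone, with its 1 time-0 array as the start, gave 303 genes late and 4 early against start, and in clone c8 alone 93 and 15; a single clone with separate time points leaves no residual degrees of freedom. Without phase means late against early gave 662 genes in clone c6 and 179 in clone c8. Except where said, the cause was not tested.

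With no replicate block, that is without the clone in the model, 369 genes varied with time, 506 changed late and 63 early against start; late against early (480) and the clone level without the time term (2135) moved less. Gene lists called with an estimated correlation numbered 6 late against start, 0 early against start and 2 late against early. With fry they numbered 16 late against start (15 higher and 1 lower), 2 early against start and 10 late against early (10 higher and 0 lower). The clone agreement of r = 0.71 became 0.623 without a filter, 0.588 and 0.763 with pseudocounts of 1 and 64, the same with probe sets kept, and 0.563 for the change from early to late.

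With single arrays left out, the counts ranged from 556 to 1190 for time, 373 to 1091 late against start, 24 to 425 early against start, 497 to 1244 late against early, 0 to 0 for the response and 2233 to 2713 for the clone level. Lists ranged from 16 to 17 late, 7 to 14 early and 14 to 16 late against early, and the agreement from 0.672 to 0.728. The largest drops came without a time-0 array: of clone c6 556, 393 and 24 genes for time, late and early against start, of clone c8 573, 373 and 47 genes and 7 early lists. Early against start gave 425 genes without time 12 of clone c6, 178 without time 4 and 152 without time 8 of clone c8, and late against early 1244 without time 12 of clone c8.

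Over the named genes and all settings other than leaving out an array, 4923 values kept their side of the threshold and, where called, their direction, 428 were no longer past it, 28 came past it and 1 reversed: TAF15 in the clone level, at -0.058 with a pseudocount of 1 against 1.63. That came with a change of its representative probe set, 1 of 32 such changes with that pseudocount, and with the probe set kept TAF15 was at 1.95. With single arrays left out, 5290 were as before, 232 were no longer past the threshold and 62 came past it. Probe sets near background carry the least information, and the pseudocount of 16 shrinks their changes.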

Other observations

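The gene list tests and the counts over other splits of the arrays were fixed beforehand; the test of fibroblast genes was chosen after the result was seen. Several gene groups not described so far moved late against start. Of 24 interferon response genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), led by IFITM2 (2.48 ± 0.32), IFITM3 (1.68 ± 0.21) and IFITM1 (1.63 ± 0.30), with a camera adjusted p of 2.65e-06 and an adjusted p of 0.0619 with an estimated correlation. Of 9 Schwann cell and glial markers 4 rose and 0 fell (the same adjusted over the list alone): CRYAB (2.37 ± 0.27), NGFR (1.09 ± 0.29), EDNRB (0.94 ± 0.22) and the neural progenitor filament NES (0.72 ± 0.11; camera adjusted p = 0.00217, adjusted p = 0.0506 with an estimated correlation). Immediate early genes were called higher (6 of 27 rose, 1 fell; 9 and 1 adjusted over the list alone; camera adjusted p = 0.000827, adjusted p = 0.128 with an estimated correlation), with the matricellular CCN1 at 2.03 ± 0.23 and SGK1 at 1.82 ± 0.30 against EGR1 at -1.55 ± 0.18. MYC rose 14.8-fold, yet the list of MYC and MYCN targets was called slightly lower (mean log2 change -0.12, 0 of 31 rose and 1 fell; camera adjusted p = 0.00126, adjusted p = 0.389 with an estimated correlation). Histone genes were called higher (3 of 8 rose, 5 adjusted over the list alone; camera adjusted p = 0.00148, adjusted p = 0.256 with an estimated correlation).

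Late against start, S phase genes were called lower (2 of 33 fell; camera adjusted p = 7.10e-09, adjusted p = 0.327 with an estimated correlation), as were p53 targets (3 of 21 fell, TP53I3 rose; camera adjusted p = 0.0323, adjusted p = 0.173 with an estimated correlation). Camera did not call the WNT response genes (adjusted p = 0.172), whereas fry did (adjusted p = 0.00580). Of these 15 genes 4 rose, among them SFRP1 at 1.59 ± 0.19 and DKK3 at 1.51 ± 0.25, and ZNRF3 fell. The camera adjusted p was 0.288 for G2 and M phase, 0.743 for apoptosis regulators, 0.743 for the integrated stress response, 0.802 for chaperones of the unfolded protein response, 0.810 for cholesterol biosynthesis, 0.505 for glycolysis and hypoxia, 0.810 for oxidative phosphorylation, 0.117 for mitochondrial translation, 0.696 for housekeeping genes and 0.269 for cytoplasmic ribosomal proteins. Markers of other cell types were not called either: melanocyte 0.743, endothelial 0.802, haematopoietic 0.802 and epithelial 0.743. At time 120 of clone c6, a single array, the 355 risen genes stood at 113% of the late change (108% at time 96) and the 35 genes that fell 2-fold or more at 115% (119% at time 96). The sign of the mean, the median and the camera test differed late against start for Notch receptors, ligands and machinery (mean 0.28, median -0.02, test up), catecholamine genes (0.03, 0.05, down), apoptosis regulators (-0.01, 0.05, down), unfolded protein response chaperones (0.01, 0.05, down), cholesterol biosynthesis (0.02, -0.05, down) and oxidative phosphorylation (0.01, 0.01, down), none of which camera called.

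Early against start, camera also called cholesterol biosynthesis (adjusted p = 0.0332), interferon response (0.00777), TGF-beta and BMP response (0.0332), Schwann and glial (0.0320), cytoplasmic ribosomal protein (7.36e-06), extracellular matrix (0.0332), axon guidance (0.00529) and fibroblast (0.0332) lists higher and MYC and MYCN targets (0.00742) lower. Of these, 5 of 21 TGF-beta and BMP genes, 5 of 33 axon guidance genes, 2 of 24 interferon genes and 1 of 9 glial markers rose, and no member of the others passed. The TGF-beta and BMP list had a mean of 0.25 and a median of -0.00. With an estimated correlation the adjusted p of these 9 lists lay between 0.319 for the glial and 0.527 for the matrix list. Late against early, camera called G2 and M phase genes lower (adjusted p = 0.000257, and 0.525 with an estimated correlation) with 0 of 30 genes passing. It called S phase genes higher (adjusted p = 0.00748, and 0.570 with an estimated correlation) with 2 of 33 risen. The late minus early change of both lists differed between the clones by camera (adjusted p = 4.86e-10 and 0.00106), though not with an estimated correlation. These pooled calls may therefore not hold in each clone.

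Stromal cells growing in the cultures were considered as a source of the late rise of smooth muscle and matrix genes. The labels name only clones of IMR32. Fibroblasts make COL1A1 and COL1A2 along with COL3A1, but the upper 95% bound of the late log2 change was 1.10 for COL1A1 and 1.03 for COL1A2 where COL3A1 rose by 7.56. That argues against fibroblasts as the source, as far as these probe sets read both genes, although 5 of 9 fibroblast markers rose, among them LUM (3.85), S100A4 (2.61) and THY1 (1.27; camera adjusted p = 3.55e-07, adjusted p = 0.0783 with an estimated correlation). MYCN, amplified in this line, changed by -0.13 (95% bounds -0.30 to 0.05) on its brightest probe set, so that signal showed no clear dilution by other cells. The dimmer MYCN probe sets above the intensity filter were at -0.36 ± 0.23, -0.47 ± 0.31 and, close to the filter, 0.08 ± 0.16, so they bound a dilution less tightly. A small share of such cells would not show in the MYCN signal, and other stromal cells were not tested. Doxycycline and time in culture stay open, because 0 arrays without NOTCH3IC followed time 0 (doxycycline or time in culture rather than NOTCH3IC cannot be told apart here).

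Other splits of the arrays into phases or clones were counted. For late against early, 2 of 100 splits drawn from the 200 possible within clones, the real one among them, gave as many genes as the 708 observed. The arrays are ordered in time and not exchangeable. Any drift with time would set the real split apart, so this count does not exclude chance. The highest other, with 773 genes, placed time 12 of clone c8 among the late arrays and time 72 of clone c8 among the early. As many lists as the 16 called were reached in 6 of 100 splits (highest other 19), so chance is not excluded for the number of lists. For the clone level, 1 of 100 splits, the real one, reached 2963 genes (highest other 667). A random exchange of the clone labels does not account for that count, although a batch that followed the clone would give the same. For the clone difference in response all 32 splits reach the 0 genes observed by construction, so this count cannot tell whether chance is at work. The highest, with 2092, exchanged the clones at all 3 late times, which turns the level difference between clones into a response and points to that structure of the samples.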
